A study of Homo sapiens with 12 samples.

How the data were processed

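RNA was measured by poly(A)-selected, stranded sequencing of 6 established esophageal cancer cell lines, TE-5, TE-6, TE-4, KYSE70, TE-1 and TE-8, numbered replicates 1 to 6. Each line gave 1 control library and 1 library after 6 h with Fusobacterium nucleatum (Fn), at a multiplicity of infection written 1:100 in the labels, without saying which term is the bacteria. Reads were trimmed with Trimmomatic 0.39 and aligned with STAR 2.7.10b to hg38, per the submitters' processing notes. The counting tool, its annotation and its use of strand are not given in the sources used here.

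The deposited table held 2 values per gene and library. Expected counts were deposited by the authors without normalization, per the file headers, and 33.5 to 39.7% of the values were not whole numbers within 0.0001. The other value was the log2 of TPM as deposited by the authors, with every value at or under 1 TPM listed as 0. Such a value was read as 0 in filters and as 1 TPM in fold changes, which understates the change of low genes. The table listed 57955 genes and no mitochondrially encoded gene. Coordinates and symbols are those of the table (hg38), and 680 of 694 list entries were matched to a gene ID through current and older symbols.

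Library totals ran from 33935177 to 53599985 counts. Expected counts were rounded to whole numbers. Genes with a mean TPM of at least 1 over the 12 libraries were tested, 17841 in all, with edgeR 4.0.16 in R 4.3.3 (TMM scaling, glmQLFit and glmQLFTest, two-sided), with the cell line as a block. Benjamini-Hochberg adjusted p-values under 0.05 were called. The plan, written before the data were examined, named limma on log2(TPM + 1) first and edgeR if the table held counts, so edgeR was used. The plan did not set edgeR's choice between its older and its bias-adjusted quasi-likelihood fit. The default of the installed version, the older fit, was kept as the main setting, at a time when the counts of calls under both were known, and the other is given as an alternative chosen after seeing the data.

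The lines pair the libraries: after the group means were removed, the correlation between the 2 libraries of a line was 0.940 to 0.966. Changes per line are differences of log2 CPM with a prior count of 2. The fitted log2 fold change weights lines by their counts and can differ from the mean of the 6 lines. Replicates are different cell lines with 1 culture per condition. The gene p-values therefore set the mean change with Fn against its variation between lines, with each gene's variance drawn toward that of other genes. That variation cannot be told apart from variation between cultures.

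The 36 gene lists were fixed before the data were examined. Lists with at least 5 tested genes, 33 in all, were tested with camera at a preset inter-gene correlation of 0.01, with an estimated correlation and fry beside it. Camera sets the members of a list against the other genes, so its p-values do not measure variation between lines. The estimated correlation of the NF-kB list was 0.60, far above the preset value. An exact sign-flip test over the 6 lines was run on each list's mean change minus the line's median change. It used all 64 flips, so its smallest two-sided p is 0.03125. The response of a single line had no replicate and no test: a gene was counted when log2((TPM + 1) with Fn / (TPM + 1) in the control) was at least 1 in size and TPM was at least 5 in either library. The number shared between lines was set against 1000 shufflings of genes within lines.

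Named genes followed a rule fixed before the data were examined. It took the 12 highest and 12 lowest called genes that moved one way in all 6 lines with a mean TPM of at least 5 in the higher group (if none passed in a direction, the 5 with the smallest p). It also took up to 4 members per list with the smallest p, CD274, CXCL8, CCL20 and IL6, and the 3 highest and 3 lowest changes per line. Genes outside it are said to be chosen after their values were seen.

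The gene test was tested on simulated data: counts for the 17841 genes were drawn from the real means, library totals and dispersions, with 200 genes changed alike in every line for the comparison of co-culture with control, and 20 more raised by 1 as a list. Of the 200 it recovered 43 of 67 genes at a log2 change of 0.5, 59 of 67 at 1 and 63 of 66 at 2. It called 18 of the 20, and 16 of its 199 calls (8.04%) were unchanged genes. Real changes were not alike in every line, with NF-kB list means from 0.40 in TE-8 to 1.78 in KYSE70. The spread of changes between lines was not compared between the simulated and the real data. Alternatives covered the block, scaling, pseudocount, filter, test and leaving out each line, with limma 3.58.1 for the planned pseudocounts, quantile normalization and array weights. DESeq2 1.42.0 and limma on log2(TPM + 1) as an alternative to edgeR were added after seeing the data. Reads shared between near-identical genes (CXCL1, CXCL2 and CXCL3, the metallothioneins, histones and HLA genes) and between overlapping genes cannot be told apart in the table, so those values are uncertain.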

Results

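Transcripts of 6 established esophageal cancer cell lines were measured after 6 h of co-culture with Fusobacterium nucleatum (Fn), an anaerobic Gram-negative bacterium of the mouth, and in control cultures without it. Each of TE-5, TE-6, TE-4, KYSE70, TE-1 and TE-8 gave 1 library per condition, 12 libraries in all. Totals ran from 33935177 counts (TE-1 control) to 53599985 (TE-8 with Fn). The comparison asks which transcripts of the cancer cells differ after contact with the bacterium.

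Co-culture with Fn was followed by higher levels of chemokines and of genes of the NF-kB pathway. Among 17841 genes, edgeR's quasi-likelihood test with the cell line as a block called 11 higher with Fn and 0 lower, against 621 higher and 536 lower at an unadjusted p under 0.05, where chance would give 892 in all. Of the 11, 6 met the rule of a rise in every line. CCL20, a chemokine that draws dendritic cells and lymphocytes, had the highest fitted change, at a log2 fold change of 6.03 (SE 0.34, adjusted p = 4.0e-05, chromosome 2, 227813842 to 227817564, hg38). It was at or under 1 TPM in every control and averaged 20.3 ± 22.4 TPM (SD, n = 6) with Fn. In TE-1 it rested on 0 counts in the control and 2 with Fn. CXCL8, the neutrophil chemokine interleukin-8, had a log2 fold change of 4.54 (SE 0.65, adjusted p = 0.045, chromosome 4, 73740506 to 73743716), from 13.7 ± 30.4 to 156 ± 182 TPM.

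CXCL1 had a log2 fold change of 3.69 (SE 0.23, adjusted p = 5.7e-05), with line values from 1.36 in TE-1 to 4.51 in TE-4. It lies on chromosome 4 at 73869393 to 73871242. TNFAIP3, which encodes the NF-kB inhibitor A20, had 3.21 (SE 0.47, adjusted p = 0.045) and lies on chromosome 6 at 137867188 to 137883312. NFKBIA, which encodes the NF-kB inhibitor IkB-alpha, had 2.13 (SE 0.25, adjusted p = 0.011) and lies on chromosome 14 at 35401511 to 35404749. BIRC3, an inhibitor of apoptosis and NF-kB target, had 1.88 (SE 0.21, adjusted p = 0.0071) and lies on chromosome 11 at 102317450 to 102339403.

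The other 5 called genes did not rise in all 6 lines. CXCL3 (log2 fold change 3.80, adjusted p = 9.0e-04) was higher in 5 lines and lower in TE-8, at −0.45. CXCL2 (3.31, adjusted p = 0.025), named after its values were seen, was higher in 5 lines, with −0.03 in TE-1. CXCL10, an interferon-inducible chemokine (4.58, adjusted p = 0.0040), was higher in 4 lines and had 0 counts in both libraries of TE-1 and of TE-8. CSF2, which encodes the growth factor GM-CSF (2.81, adjusted p = 0.025), was higher in 5 lines and had 0 counts in both libraries of TE-6. UBD, a ubiquitin-like protein (3.61, adjusted p = 0.033), was higher in 5 lines and is named after its values were seen. It went from 11 to 188 counts in TE-5, had at most 13 counts in any library of the other lines, and had 0 in both TE-8 libraries. Reads of CXCL1, CXCL2 and CXCL3 cannot be told apart with certainty between these near-identical genes.

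The calls depended on the method. Limma on log2(TPM + 1) with the same block called 0 genes (1299 at an unadjusted p under 0.05). Its input differed too, being TPM without TMM scaling and with values at or under 1 read as 1. Its 0 calls therefore cannot be put down to the test alone. EdgeR without the block also called 0 genes (28 at an unadjusted p under 0.05). DESeq2 called 30 higher and 3 lower and edgeR's bias-adjusted fit 29 higher and 1 lower. Without TE-5 4 genes were called, all among the 11. Without TE-6 7 were called (6 of the 11), without TE-4 6 (5 of the 11), without TE-1 9 (9 of the 11), without TE-8 11 (8 of the 11) and without KYSE70 16 (11 of the 11).

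**Figure D1:**
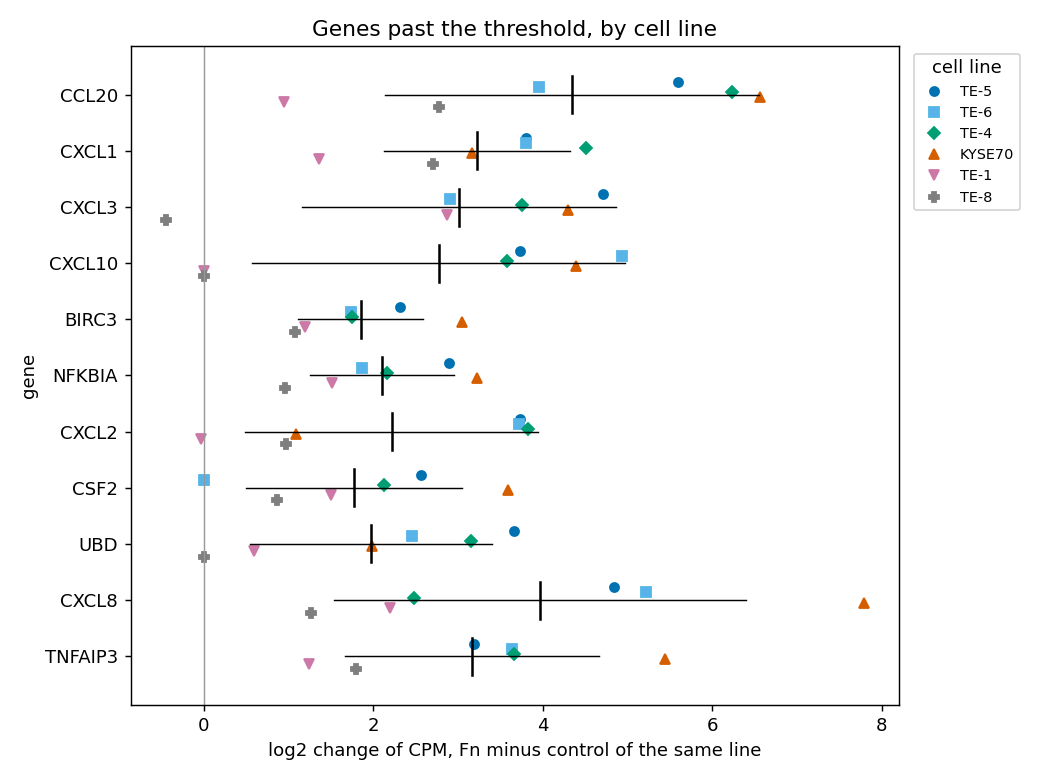
Log2 change of CPM (Fn minus control of the same line, x axis) for the 11 called genes (y axis); each symbol is 1 cell line, the vertical bar is the mean and the horizontal bar 1 SD over 6 lines. TE-1 and TE-8 lie at the low end for most genes, and CXCL8 in KYSE70 is the highest point at 7.79.

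NF-kB feedback and target genes were higher as a list. All 22 measured members had a fitted change above 0, 3 passed over all genes tested, and 21 passed when adjusted over the list alone. The mean change was 1.08 ± 0.58 (SD, n = 6 lines), positive in 6 of 6 lines (camera adjusted p = 1.5e-69; adjusted p = 0.051 with an estimated correlation; exact sign-flip p = 0.03125, adjusted 0.147). Beside the 3 called genes, CD83 had a log2 fold change of 1.43 and RELB, named after its values were seen, 1.88, with adjusted p = 0.080 and 0.083. Chemokines rose too, with a mean of 1.85 ± 1.03, 6 of 13 members called and 8 when adjusted over the list alone (camera adjusted p = 4.3e-48; adjusted p = 0.021 with an estimated correlation). This was the 1 list of 33 that kept its call with an estimated correlation; it lost it with fry (adjusted p = 0.10), as all lists did, and its sign-flip p was 0.03125 (adjusted 0.147).

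Inflammatory cytokines averaged 0.98 ± 0.89 over the 6 lines (camera adjusted p = 2.4e-17; adjusted p = 0.17 with an estimated correlation). CSF2 passed over all genes, and 9 of 17 members passed when adjusted over the list alone. IL1A had a log2 fold change of 2.24 and IL1B 3.52, with adjusted p of 0.26 and 0.42. IL1B had 122 counts in the KYSE70 control and 6139 with Fn, and had 0 counts in both TE-1 libraries. Immediate-early and AP-1 genes averaged 0.51 ± 0.49 (camera adjusted p = 4.5e-26; adjusted p = 0.17 with an estimated correlation). None of the 28 passed over all genes and 15 passed when adjusted over the list alone, among them JUN (1.06), JUND (0.35), ATF3 (0.80) and DUSP1 (0.52).

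Interferon-stimulated genes had a mean of 0.22 ± 0.41 and were not alike between lines: 0.89 in TE-6, 0.53 in TE-5 and −0.21 in TE-4 (camera adjusted p = 7.2e-08; adjusted p = 0.40 with an estimated correlation; exact sign-flip p = 0.31). None of 28 members passed over all genes or when adjusted over the list alone, and IFIT3, at 0.52, had the smallest p. Antigen presentation genes averaged 0.09 ± 0.20 (camera adjusted p = 8.9e-05, with 0.39 at an estimated correlation, 0.062 without TE-5 and 0.083 without the block). TE-5 carried much of that mean, at 0.47 against 0.16 or less in the other lines (exact sign-flip p = 0.34). Among the members, TAP1 was at 0.34 and B2M at 0.16. Both passed when adjusted over the list alone.

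Apoptosis regulators averaged 0.18 ± 0.12 and were positive in 6 of 6 lines (camera adjusted p = 1.9e-05; adjusted p = 0.17 with an estimated correlation). BIRC3, which is also in the NF-kB list, was called and carried much of that mean: without it the list averaged 0.08 ± 0.08, above 0 in 5 of 6 lines (adjusted p = 0.0064, an alternative chosen after seeing the data). BIK (0.46) and BID (0.18), which promote apoptosis, passed when adjusted over the list alone. Matrix proteases and the plasminogen system averaged 0.24 ± 0.21 in 6 of 6 lines (camera adjusted p = 3.8e-04; adjusted p = 0.17 with an estimated correlation and 0.074 with quantile normalization), led by PLAU (0.96), the urokinase gene, and the collagenase MMP13 (0.54). Neither passed over all genes.

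Smaller list changes passed camera's preset test. Heat shock genes averaged 0.05 ± 0.07 (adjusted p = 4.4e-04; adjusted p = 0.29 with an estimated correlation and 0.18 without the block), metallothioneins 0.20 ± 0.33 (adjusted p = 0.0064; adjusted p = 0.30 with an estimated correlation, 0.052 without the block and 0.23 without TE-8) and p53 targets 0.13 ± 0.12 (adjusted p = 0.034; adjusted p = 0.19 with an estimated correlation, 0.17 without TE-5, 0.086 without TE-6 and 0.28 without TE-4). GADD45A, at 0.47, was the p53 target with the smallest p. Of the 20 p53 targets, 11 had a fitted change above 0 and 9 below, with a median of 0.04, so they did not rise as a group. Replication-dependent histones were the 1 list called lower, at −0.15 ± 0.35 (adjusted p = 0.034; adjusted p = 0.62 with an estimated correlation, 0.062 without TE-5, 0.13 without TE-6 and 0.57 without KYSE70), with −0.79 in KYSE70.

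The other 21 lists were not called. They include innate sensors (adjusted p = 0.098), EGFR ligands (0.092), immune checkpoint ligands (0.36), hypoxia and glycolysis (0.34), the unfolded protein response (0.20), mitosis genes (0.44), squamous differentiation (0.69) and autophagy (0.56). Markers of fibroblasts (adjusted p = 0.79) and of columnar epithelium (0.36) were not called either. Lists of leukocytes and endothelium had 2 and 3 tested members and were not tested.

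**Figure D2:**
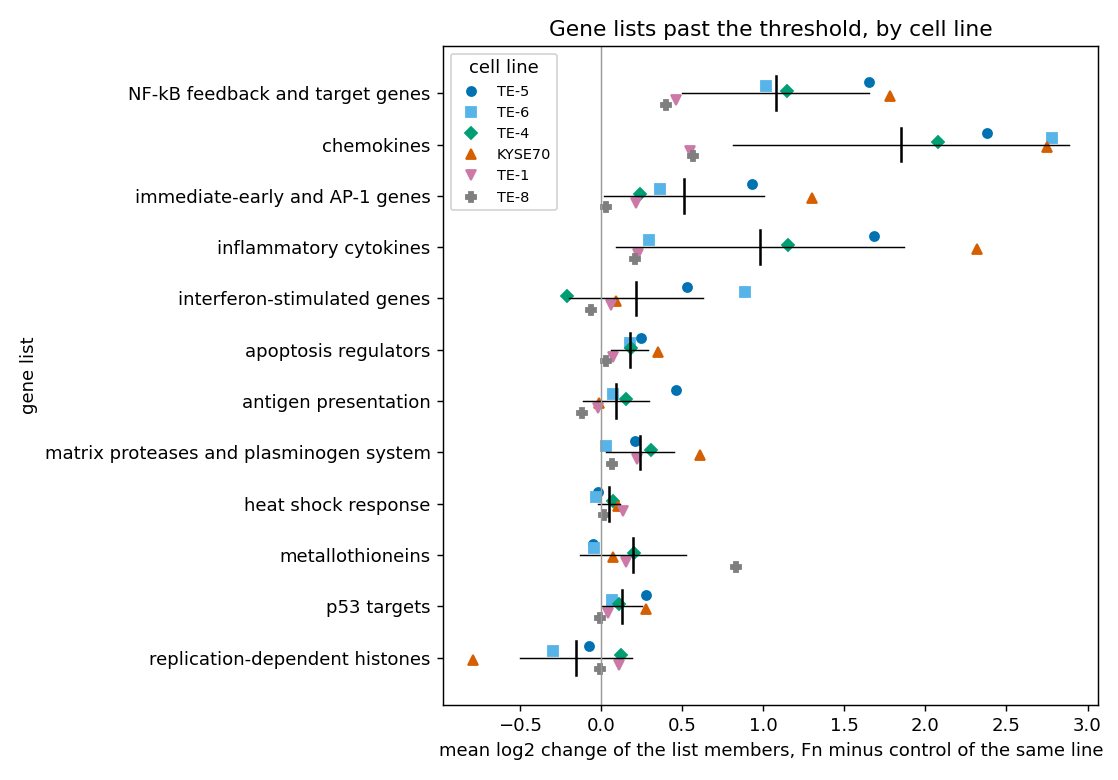
Mean log2 change of the members of each called list (Fn minus control of the same line, x axis; lists on the y axis); each symbol is 1 cell line, the vertical bar is the mean and the horizontal bar 1 SD over 6 lines. NF-kB genes and chemokines lie above 0 in every line, and interferon-stimulated genes run from −0.21 in TE-4 to 0.89 in TE-6.

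CD274, which encodes PD-L1, had a log2 fold change of 0.24 (SE 0.15, adjusted p = 0.84) and was higher in 3 of 6 lines. IL6 had 1.51 (SE 0.48, adjusted p = 0.69) and was higher in 5 of 6 lines. No gene passed in the lower direction. The 5 lower genes with the smallest p were SLC39A10, a zinc importer (−0.28, adjusted p = 0.082, lower in 6 of 6 lines), CYP1A1 (−0.50, 0.23, 5 of 6), NOTCH3 (−0.24, 0.23, 6 of 6), ADAMTS15 (−0.34, 0.26, 6 of 6) and SNORA40 (−3.78, 0.31, 6 of 6). SNORA40 here is ENSG00000253047, which rested on 8 counts or fewer per library; another tested gene has the same symbol.

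The lines differed in how many genes moved, as a description of 1 pair of libraries each. KYSE70 had 239 genes higher and 75 lower by a log2 change of at least 1, TE-5 118 and 66, TE-4 66 and 46, TE-6 57 and 41, TE-1 35 and 55, and TE-8 22 and 24. The mean NF-kB list change was 1.78 in KYSE70 and 1.65 in TE-5, against 0.47 in TE-1 and 0.40 in TE-8. Differences between lines were not tested.

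The 3 highest changes were CXCL8, CCL20 and CXCL1 in TE-5, CXCL8, DNAJC25-GNG10 and CXCL1 in TE-6, and CCL20, CXCL1 and the pseudogene ENO1P1 in TE-4. In KYSE70 they were CXCL8 (7.15), IL1B (5.68) and TNFAIP3 (5.28). No chemokine was among the 3 highest of TE-1 or TE-8, which were led by MIR429 (2.32, from 0 to 8 counts) and AL022067.1 (4.61). The lowest changes were mostly small RNAs, pseudogenes and genes without a standard symbol, such as AL022067.1 in TE-5 (−5.05) and SNORD58B in TE-1 (−4.72).

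The lines shared more of their higher genes than shuffling gave. TNFAIP3 reached a log2 change of 1 in 6 lines, CXCL1 and NFKBIA in 5, and 6 genes in 4 (PTGS2, CXCL8, CXCL3, NFKB2, BIRC3 and RELB), where 1000 shufflings gave no gene in 4 or more. PTGS2 encodes cyclooxygenase-2. Of the lower genes 19 were shared by 2 lines, where the shufflings gave at most 8 (mean 2.31), 2 by 3 lines, where they gave at most 1 (mean 0.01), and 0 by 4. The 2, named after their values were seen, were SNORD63 (ENSG00000222937), with 19 counts or fewer per library, and CTD-2616J11.11, which fell from 81 to 0 counts in TE-5 and from 45 to 0 in TE-1. Shuffling treats all genes as equally noisy, so exceeding it does not by itself show a shared response, higher or lower. Over all tested genes the changes of 2 lines were weakly related, with Pearson r from 0.01 to 0.17 over the 15 pairs. Spearman rho ran from −0.06 to 0.18, so it was below 0 for some pairs. Both are taken across genes, which are not independent replicates.

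**Figure D3:**
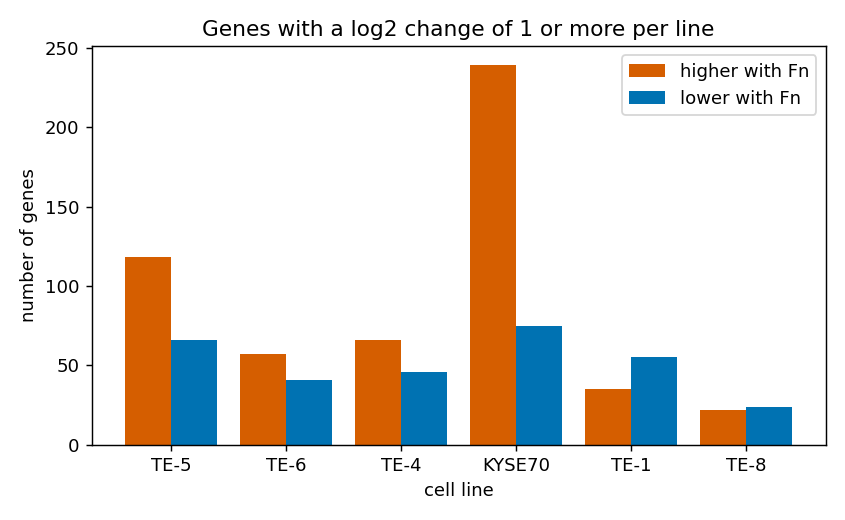
Number of genes (y axis) with a log2 change of TPM + 1 of at least 1 and a TPM of at least 5 in either library, per cell line (x axis), higher with Fn and lower with Fn. KYSE70 has 239 higher and TE-8 has 22, each from 1 pair of libraries.

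The cell line set most of the variation between libraries. It held 97.4% of the variance of log2(TPM + 1), and the condition 0.616%. The closest library of all 12 was the other library of its line, with Pearson r of 0.987 to 0.995 within lines and at most 0.868 between lines.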

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

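The tests of library depth, of low counts, of the baseline line by line and of RNAs without a tail in other lines were chosen after the result was seen; the other tests of this part were written before their values were seen. In 86 sets of 6 values, 11 had a value far from the rest, where chance would give about 4.3.

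The response was smaller in TE-1 and TE-8, with NF-kB list means of 0.47 and 0.40 against 1.02 or more in the other 4 lines. For TE-8, shallower libraries as the cause are argued against by its smaller library, which held 50215635 counts. For TE-1 they stay open, since its smaller library held 33935177 counts, the lowest total of all, though TE-5, with a smaller library of 35685341 counts, had a list mean of 1.65. Counts too low to show a fold are argued against by the 3 list members with at least 5 log2 CPM in all controls, whose mean change was at most 0.17 in TE-1 and TE-8 and at least 0.67 in the others, a test on few genes. A high baseline stays open: the control level of the list was 0.53 log2 units higher in TE-1 and TE-8 than in the others, which TE-1 carried. TE-1, at 4.97, lay above every other line but only 0.26 (SE 0.21, 22 genes) above TE-5, which responded with a mean of 1.65. TE-8, at 3.98, differed from TE-5 by −0.72 (SE 0.38) and also lay below TE-4 (4.30, list mean 1.15), which goes against a high baseline there, by less than 2 SE. These SEs are over the 22 genes of 2 single control libraries, which are not independent replicates, and do not measure variation between cultures. A difference between the cell lines themselves stays open and untested.

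Interferon-stimulated genes had list means of 0.53 in TE-5 and 0.89 in TE-6, against −0.21 in TE-4 and 0.09 in KYSE70. The means of TE-1 and TE-8 were 0.07 and −0.06. These are differences between single pairs of libraries and were not tested. Loss of the interferon genes at 9p21, read from their neighbour MTAP, is argued against by 13.5 TPM of MTAP or more in the TE-4 and KYSE70 controls, while TE-6, with the highest mean, had 0 counts of MTAP. A high baseline is argued against too: the higher of TE-4 and KYSE70 lay at −1.56 log2 units from the lower of TE-5 and TE-6. The control means were 1.93 log2 CPM in TE-4 and −0.23 in KYSE70, against 4.48 in TE-5 and 3.49 in TE-6. Some members had few counts in those 2 lines, such as IFIT1 with 2 in the TE-4 control and 32 in that of KYSE70. Whether low counts hide a change there was not tested. A candidate explanation is interferon made in the culture: IFNB1, IFNL1, IFNL2 and IFNL3 together had 52 counts in TE-5 and 17 in TE-6 with Fn (15 and 4 in their controls) and 0 in both libraries of the other 4 lines. With interferon counts in only 2 lines, this remains a hypothesis.

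Replication-dependent histones were lower in KYSE70 with Fn, at −0.79. Less RNA without a poly(A) tail in that library could account for it, since histone transcripts lack the tail. The median change of 11 other such RNAs was −0.29, from −1.66 for RN7SK to 0.36 for SCARNA10 (ENSG00000239002), which lies between the values that would speak for and against it. The median was −0.50 in TE-5 and −0.47 in TE-6, where the histone list changed by −0.07 and −0.29, but these RNAs went both ways in every line, and RN7SL2 rose by 1.17 in TE-6 and fell by 1.18 in KYSE70. A median over them therefore decides nothing, and the explanations cannot be told apart. No biological explanation was tested.

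CXCL3 in TE-8 lay far below the other lines at −0.45, as did BIK in TE-8 (0.0076) and BID in TE-1 (0.023), while IFIT3 in TE-6 lay far above at 1.37. Metallothioneins lay far above in TE-8, at 0.83. In KYSE70 the EGFR ligands (0.92), the Wnt targets (0.38) and the junction and adhesin partner genes (0.33) lay above the other lines. Immune checkpoint ligands stood out in TE-5 (0.33) and NRF2 targets in TE-4 (0.095). Among the Fn libraries, the total of TE-8 stood out at 53599985 counts.

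Outside the tested genes, 4 were at 5 TPM or more with Fn and at or under 1 TPM in the control of a line, and 7 were the reverse. The 4, named after their values were seen, were TNFSF18, TNF and ENSG00000259371 in KYSE70 and MIR3142HG in TE-5. TNF, the cytokine, went from 0 to 86 counts in KYSE70 and from 4 to 77 in TE-4.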

How the results depend on the processing

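DESeq2, limma on log2(TPM + 1) as an alternative to edgeR, the bias-adjusted edgeR fit and lists without the called genes were chosen after seeing the data. Of the 11 higher genes, 9 were called with median-ratio scaling and 9 without the trend, 11 with a log2 fold change of at least 1, and 5 with robust fitting. A mean TPM of at least 5 called 5 genes from fewer tested genes and no filter 20. Without the replicate block 0 genes were called. Limma called 0 at pseudocounts of 0.1, 0.5, 1 and 5, 0 with quantile normalization and 0 with array weights. These limma fits all used TPM with values at or under 1 read as 1, in place of counts. DESeq2 called 30 higher and 3 lower, the bias-adjusted fit 29 higher and 1 lower, and an adjusted p under 0.10 18 higher and 1 lower. In 1 direction in all 6 lines were 414 higher and 440 lower genes, where chance gives 558 together. Leaving out 1 line at a time gave 4 to 16 higher genes and 0 lower; 4 were left without TE-5. The 11 were all among the DESeq2 and bias-adjusted calls. For these differences the cause was not tested, except that fewer genes or lines entered some fits. The number of lists called was 9 to 13 in the alternatives other than an estimated correlation (1) and fry (0). The p53 list lost its call in 10 of 17 alternatives and the histone list in 6, among them leaving out KYSE70. Antigen presentation lost its call without TE-5 (adjusted p = 0.062) and without the block (0.083), metallothioneins without TE-8 (0.23) and without the block (0.052), heat shock genes without the block (0.18) and with quantile normalization (0.071), and matrix proteases with quantile normalization (0.074). Calls gained were EGFR ligands without the block (0.014) and without TE-1 (0.044), innate sensors without the block (0.032), Wnt targets at a mean TPM of at least 5 (0.034) and ribosomal proteins without KYSE70 (2.0e-07). With the called genes left out of the lists the same 12 lists were called. No call reversed for a list or for the 44 named genes that were refitted; genes named for their counts or their change in 1 line were not. The 844 gene changes counted over the 6 lines became 353 at a pseudocount of 5, 1434 at 1 TPM and 2451 at a 1.5-fold size. Removal of mitochondrial genes was not run because the table lists none. Counts of 0 in TE-1 and TE-8 limit what CXCL10 can show there.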

Other observations

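The tests of the sensors as explanation and of regrouped libraries were added after the result was seen. Below the threshold lay 8 genes at an adjusted p between 0.05 and 0.10, named after their values were seen. SLC39A10 was lower. The 7 higher ones were MAP3K8, CD83, KYNU, RELB, PTGS2, SOD2 and HDAC9, each higher in 6 of 6 lines, with log2 fold changes from 0.56 (KYNU) to 1.88 (RELB). SOD2 encodes the mitochondrial superoxide dismutase and KYNU an enzyme of tryptophan breakdown. The autophagy receptors OPTN (0.55) and SQSTM1 (0.32) passed when adjusted over the autophagy list alone, as did CD47 (0.21) in the checkpoint list, while that list's VSIR, listed under its older symbol C10orf54, was lower (−0.20).

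Bacterial sensors differed between control cultures, as values chosen after they were seen. TLR2 had 435 counts in TE-5, 112 in TE-6, 56 in TE-4, 10 in TE-8 and 0 in KYSE70 and TE-1, and KYSE70 had the highest NF-kB list mean, 1.78. MB21D1, which encodes the DNA sensor cGAS, had 0 counts in the TE-4 control and 18 in KYSE70, against 600 or more in the other lines. JAK1, a kinase of interferon receptors, had 310 counts in the KYSE70 control and 3311 or more elsewhere. CDKN2A and CDKN2B had 0 counts in both libraries of TE-6, KYSE70 and TE-8.

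The hypothesis, set before the data were examined, that control levels of a sensor or adhesin receptor go with the NF-kB list change was tested for 6 genes over the 6 lines with an exact permutation test over all pairings. The smallest adjusted p was 0.75. TLR2 had Pearson r of 0.50 (exact permutation p = 0.37) and Spearman rho of 0.33 (p = 0.53), and r was 0.20 without the 2 lines farthest from the median. For ALPK1, the sensor of bacterial ADP-heptose, r was −0.39 (exact permutation p = 0.46) and rho −0.26 (p = 0.66), and r was 0.90 without its 2 farthest lines. The other values of r were −0.02 for TLR4, −0.26 for NOD1, 0.35 for CDH1 and 0.30 for CEACAM1, none with an adjusted p under 0.75. TLR2 and TLR4 were at or under 1 TPM in the KYSE70, TE-1 and TE-8 controls, and CEACAM1 in those of KYSE70 and TE-8. Such values were all read as 1 TPM and so were tied. The 6 lines and these ties leave wide room for a relation, so none is excluded.

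Labels were exchanged within lines in all 32 ways that part every pair. The real labels called 11 genes and the highest other labelling 3, so 1 of 32, the real one, gave as many. That share, 0.03125, is the smallest that 32 labellings can give. The exchanges therefore argue against chance for the gene count but cannot exclude it. For the lists they do not argue against it: the real labels called 12 and the highest other labelling also 12. In all, 3 of 32, the real one included, gave as many lists. The median of the other labellings was 6 lists. By list, the real labels gave the smallest camera p of the 32 for NF-kB genes, chemokines, inflammatory cytokines, apoptosis regulators and matrix proteases. For matrix proteases the margin was narrow, at a camera p of 9.1e-05 against 9.7e-05. The other called lists had several labellings with a p as small, the real one included. These were 2 for immediate-early genes, 2 for heat shock genes, 3 for p53 targets, 4 for antigen presentation, 5 for metallothioneins, 12 for interferon-stimulated genes and 12 for histones.

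Of the 462 splits into 6 and 6, 452 could be fitted with the block, and 100 of these were used, the real one among them. Of the 100, 4 gave 11 genes or more, the real one and 3 others with 13, 211 and 211. For the lists 19, the real one included, gave 12 or more. The highest other count, 18, came from the same 2 splits that gave 211 genes. Some others of the 19 also parted their pairs all as labelled or all exchanged. They hold the real contrast in part of the lines, so this share is not a chance rate for the lists. The split with 13 genes parted the TE-4 and KYSE70 pairs, 1 of them as labelled and 1 exchanged. The 2 splits with 211 genes parted the TE-5 and KYSE70 pairs as labelled and kept the other lines whole, so that their contrast was Fn against control in those 2 lines, which had the most changed genes, 184 in TE-5 and 314 in KYSE70. With the line as a block, these 2 splits fit the same contrast and are not separate evidence. The split with 13 shows that opposed labels in 2 lines can give as many genes as the real ones. The exchanges within lines are the closer comparison.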
